A study of Arabidopsis thaliana with 12 samples.

How the data were processed

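Total RNA of seedlings was depleted of rRNA and sequenced in 12 libraries, 3 for each of Col-0 in the dark, Col-0 in red light, rrc1-3 in the dark and rrc1-3 in red light, per the labels. Samples were extracted with a column kit and libraries made with a commercial kit, per the labels' protocols. Reads were aligned with TopHat2 (version not given) to TAIR10, per the submitters' processing notes. The coordinates of the splicing tables were checked against the reference used here, in which 98.6% to 99.0% of the listed introns began with GT and ended with AG.

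The deposited expression tables have the column layout of Cuffdiff, and each holds 1 FPKM value per group over its replicates, scaled by the authors within the pair of groups. The log2 fold change, the test score, the p-value and the q-value of each gene are as deposited by the authors. These tables hold genes called by the authors only, with no values per library. The choice made before the data were examined was an edgeR test on counts of genes, with the authors' own calls as the fallback, and the fallback was used. Expression values were therefore copied, and no test of single genes was run. A group's FPKM differed between tables by a median factor of 1.04 (rrc1-3, dark) and 0.972 (rrc1-3, red light), so values were compared within tables only.

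The deposited splicing tables have the column layout of ASpli, with counts of reads per junction or exon-intron boundary and library, per the file headers. The fraction of inclusion or retention per group, its difference (a score), the log2 change of the feature, the p-value and the FDR are as deposited by the authors. The tables list features with an FDR under 0.05 and a difference of at least 0.03. Columns X4 to X6 were read as libraries 1 to 3 of the second group. The deposited fraction was recomputed from the counts and agreed within 1e-06 in 99.5% to 99.9% of features. Pathway tables give a fold enrichment and a p-value per pathway as deposited by the authors. Ontology tables were not used, since for 240 to 273 terms per table over 50% of the background genes of the term were also counted in the list tested.

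Retention was computed per library as boundary reads (mean of both boundaries) over boundary plus spliced reads, and inclusion in the same way from junctions, and given as mean and SD of 3 libraries. A junction test was added after the files were seen. It compared inclusion with exclusion reads between groups in edgeR 4.0.16 (R 4.3.3; estimateDisp, glmQLFit, glmQLFTest), and gave the log2 change in odds. Its p-values were adjusted by Benjamini and Hochberg over the listed features, which is not a false discovery rate over the genome. Features were listed because the real groups differ, so a high count of calls is built in. The difference of light responses was tested in edgeR as an interaction over all 12 libraries on the 2349 features listed in both genotype tables with the same junctions. On data simulated from the real means, the junction test recovered 24% (dark), 26% (red light) and 70% (light response) of changes of 1 in log2 odds, and 82%, 87% and 91% of changes of 2. At each size 100 features were changed, fewer than the 3353, 3453 and 731 that passed in the real data. The adjustment was therefore stricter in the simulation. All simulated features also had the same fixed dispersion, below the common dispersions of 0.0229 to 0.0268 estimated from the data. For both reasons these rates do not give the power of the test as run. Median reads per feature and library were 117 to 177 in the dark table, 123 to 186 in the red light table and 204 to 397 in the light response table. Libraries with the same replicate number in the 2 groups of a table correlated at -0.0347 to 0.0693 after the group means were taken out, so replicate numbers were not treated as pairs.

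Gene lists were written before the data were examined. Counts of members were planned, and the two-sided Fisher's exact test of higher against lower members relative to other called genes was added after the files were seen, adjusted over 37 tests. The number of members expected to be higher came from a logistic regression of direction on GC content and the logarithm of exon length, their squares and their product, over called nuclear genes (scikit-learn 1.9.0). Genes are named by a rule fixed in advance: the 8 largest rises and falls among called genes above the median level, and up to 4 members per list. For splicing it takes the 8 features with the smallest deposited adjusted p and up to 4 features of each of 4 lists. Genes that changed in opposite directions between conditions, and the other parts of the RRC1 transcript, were named after their values were seen. Intron numbers follow the direction of transcription in the longest annotated transcript that holds the intron. Reads of overlapping genes may be shared, since no strand is stated. Analyses used Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

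Alternatives were an adjusted p under 0.01, a log2 change of at least 1, a minimum support of 20 reads, 1 feature per gene, leaving out each library, the replicate block and gene or feature subsets. The subsets by place, small RNA genes, organelle genes and the junction test were chosen after the data were seen.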

Results

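Seedlings of Arabidopsis thaliana were profiled by sequencing of rRNA-depleted RNA in 12 libraries, which fell into 4 groups of 3. The wild type Col-0 and the mutant rrc1-3, a line in the Col-0 background with an altered RRC1 gene, were grown in the dark for 4 days. Both genotypes were collected in the dark or after 3 h of red light at 7 µmol per square metre per second. RRC1 encodes a serine/arginine-rich-like RNA-binding protein named for weak responses to red light, and SFPS is a splicing factor. The design asked how splicing differed between mutant and wild type in each condition, and tables of red light against dark in rrc1-3 were also used. The authors' deposited expression tables give 1 pooled FPKM (fragments per kilobase and 1e6 mapped fragments) per group, so the depth behind expression values is unknown. The splicing tables give reads per junction and library. Listed features held 1486593 to 1944410 reads per library in the dark table, 1723632 to 2553003 in the red light table and 332320 to 614748 in the light response table. These sums cover the listed features, not whole libraries. At most 3.08% of features had identical spliced reads in any 2 libraries of a group, so each library was counted separately. The labels do not say that replicates came from separately grown cultures. The edgeR and permutation p-values therefore measure the spread between these samples, which may be technical. Fisher's exact and binomial tests were run across genes or features, and their p-values measure no spread between libraries.

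The mutated gene was examined first, in each library. RRC1 (AT5G25060, chromosome 5, minus strand) carried almost no normally spliced reads across intron 15 of 16 in rrc1-3. This coding intron (chromosome 5, 8634834 to 8635302, 469 nt, TAIR10) was retained in 92.3% ± 5.30 of reads in rrc1-3 in the dark against 3.88% ± 0.926 in Col-0 (SD, n = 3 each). In red light the values were 93.2% ± 4.43 against 2.98% ± 2.14 (SD, n = 3 each). The odds of retention differed by log2 changes of 8.27 in the dark (edgeR adjusted p = 1.58e-11) and 8.68 in red light (edgeR adjusted p = 2.26e-09). Spliced reads numbered 173 to 237 per library in Col-0 and 2 to 12 in rrc1-3 in the dark, and 165 to 181 against 3 to 20 in red light, so each library went with its label. Retention counts reads over each boundary, so it does not show that the whole intron was read through in rrc1-3.

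**Figure D1:**
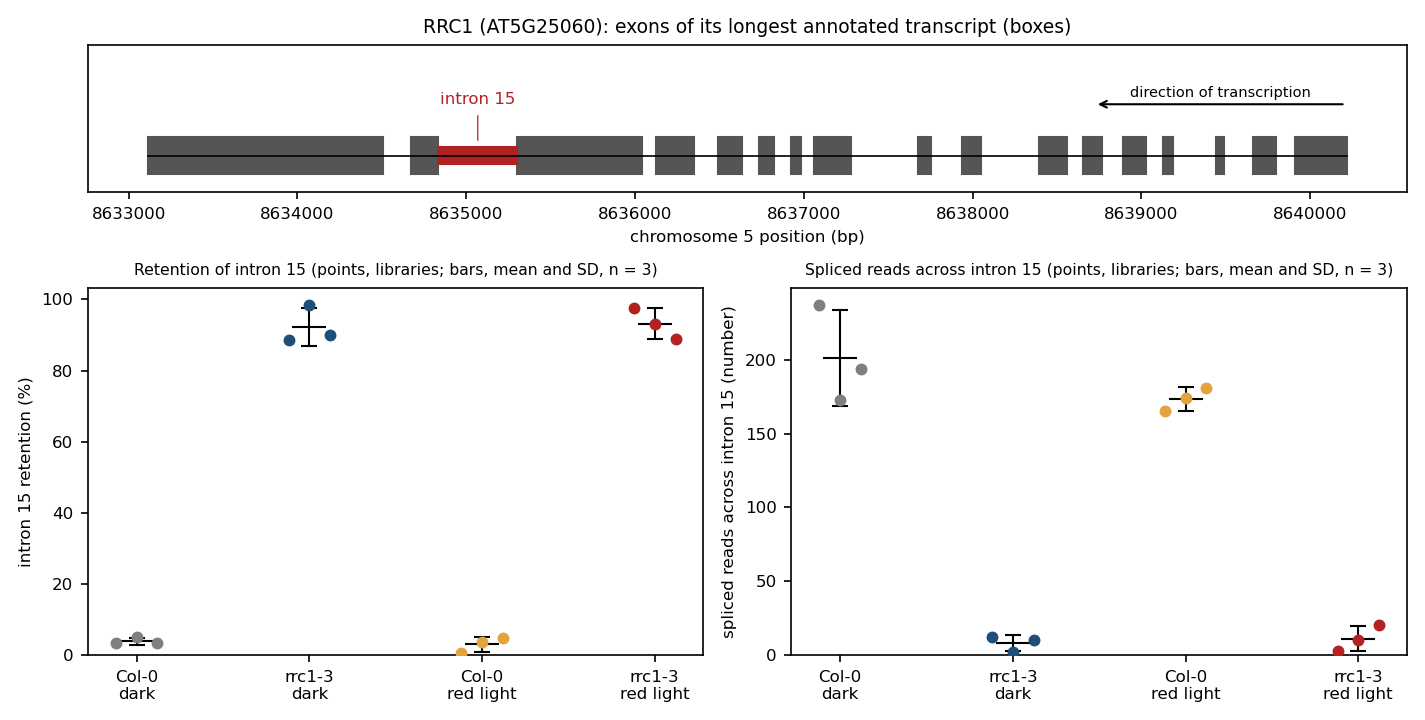
Top, exons of RRC1 (boxes) along chromosome 5 (bp), with intron 15 in red and the direction of transcription as an arrow. Bottom, retention of intron 15 (%) and spliced reads across it (number) per library (points) with group means and SD (bars, n = 3); rrc1-3 libraries held 2 to 20 spliced reads and Col-0 libraries 165 to 237.

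Other parts of the RRC1 transcript changed as well. Spliced reads across intron 16, the last of the transcript, numbered 1073 ± 265 in rrc1-3 against 205 ± 22.6 in Col-0 in red light (SD, n = 3 each). Across intron 14 they numbered 257 ± 24.8 against 120 ± 4.36 in red light (SD, n = 3 each), so reads rose unevenly along the gene. Whether splicing itself changed at intron 15 was therefore not settled. Retention of intron 14, on the 5′ side of intron 15, was 18.8% ± 0.927 in rrc1-3 and 8.27% ± 0.337 in Col-0 in the dark (SD, n = 3 each). Retention of intron 2 was lower in the mutant, at 8.21% ± 0.494 against 14.0% ± 1.01 in the dark (SD, n = 3 each). Inclusion of exon 3, of 46 nt, was 95.2% ± 3.02 in rrc1-3 and 75.9% ± 1.77 in Col-0 in red light (SD, n = 3 each). Neither RRC1 nor SFPS appeared among the genes called in the authors' deposited expression tables.

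The comparison of rrc1-3 with Col-0 in the dark asked which genes differed before any light was given. Of 41 photosynthesis genes 27 were called higher in rrc1-3, and of 31 auxin and growth genes 14 were called lower, per the authors' deposited table. Both lists split otherwise than other called genes did (two-sided Fisher's exact test, adjusted p = 0.000103 and 0.0294). This test takes no account of gene composition. From GC content and exon length alone, 19.2 of 29 called photosynthesis genes would be higher, against 27 observed. For auxin and growth genes it would be 6.50 of 18, against 4 observed, so much of that split could follow from composition. FSD1, an iron superoxide dismutase of plastids, stood at 303 FPKM in rrc1-3 and 14.7 in Col-0, 20.6-fold higher, in the authors' deposited table. CHS, the chalcone synthase that opens flavonoid synthesis, was also higher (8.59 against 0.855 FPKM) in the authors' deposited table. The same authors' deposited table held 5630 genes at its q threshold of 0.05, 3114 higher and 2516 lower in rrc1-3, of which 1441 and 1068 differed by at least a log2 of 1.

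Of 41 nuclear genes of light harvesting and the photosystems, 27 were higher, 2 lower and 12 not listed in the authors' deposited table. The split between higher and lower differed from that of other called genes (two-sided Fisher's exact test, adjusted p = 0.000103 over 37 list tests). From GC content and exon length alone, 19.2 of the 29 called members would be higher. RBCS1B, a small subunit gene of Rubisco, was 5.54-fold higher, and the antenna genes LHCB1.2 and LHCB1.3 were 4.29-fold and 3.76-fold higher, in the authors' deposited table. LHCB1.4 fell by 3.57 on the log2 scale (25.9 to 2.17 FPKM) in the authors' deposited table. These antenna and Rubisco genes have near-identical copies, so reads could be shared among them and their single values are uncertain. Of 17 chlorophyll synthesis genes, 10 were higher and 1 lower in the authors' deposited table (adjusted p = 0.0779, Fisher's exact test, with 7.44 of 11 higher from GC content and length). PORB, PORA and PORC, the light-dependent protochlorophyllide oxidoreductases, rose by log2 changes of 2.11, 1.84 and 1.75 in the authors' deposited table, and DVR, a divinyl reductase, by 1.95.

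Of 25 clock genes, 9 were lower and 2 higher in the authors' deposited table (adjusted p = 0.0521, Fisher's exact test, with 6.70 of 11 higher from GC content and length). CDF1, a repressor of CONSTANS, fell by 2.39, and the Myb factors RVE1 and RVE8 by 1.41 and 1.38 on the log2 scale in the authors' deposited table. LNK2, a coactivator of the RVE factors, fell by 1.18 in the authors' deposited table. Among 31 auxin response and growth genes, 14 were lower and 4 higher in the authors' deposited table (adjusted p = 0.0294, Fisher's exact test, with 6.50 of 18 higher from GC content and length). IAA2 fell from 606 to 246 FPKM, and SAUR15, IAA5 and PRE1 fell by 1.26, 1.19 and 1.03 on the log2 scale, in the authors' deposited table. Of 12 flavonoid and photoprotection genes, 8 were higher and 1 lower in the authors' deposited table (adjusted p = 0.106, Fisher's exact test, with 5.87 of 9 higher from GC content and length). FLS1, a flavonol synthase, and its activator MYB111 rose by log2 changes of 3.16 and 3.07 in the authors' deposited table, from levels under 1 FPKM.

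Of 35 light signalling genes, 3 were lower and 2 higher in the authors' deposited table (adjusted p = 0.816, Fisher's exact test). HFR1, a bHLH factor of phytochrome signalling, fell by 1.13 and BBX22 by 0.98, while DET1 and PIF3 rose by log2 changes of 0.83 and 0.80 in the authors' deposited table. Of 20 serine/arginine-rich (SR) splicing factors, RS2Z33 alone was listed, lower by a log2 of -0.72 in the authors' deposited table. Of 27 other splicing factors, GRP7 and PTB3 rose by log2 changes of 1.27 and 0.64, and U2AF65b and LSM5 fell by 0.63 and 0.60 in the authors' deposited table.

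All 23 plastid-encoded genes called were higher in rrc1-3 in the authors' deposited table (adjusted p = 1.76e-05, Fisher's exact test), among them RPL33 (log2 change 2.23), RPL32 (1.66) and PSBK (1.52). Plastid 23S rRNA (RRN23S.2), a target of rRNA depletion, stood at 36.7 FPKM in rrc1-3 and 0.0150 in Col-0 in the authors' deposited table. This rRNA is among the 23 genes, and rRNA depletion that differed between genotypes was not told apart from the mutation. No share from GC content and length was computed for plastid genes. Genes on shared transcripts would not be independent in the Fisher's exact test. Of the 15 mitochondrial genes called, 11 were higher and 4 lower in the authors' deposited table (adjusted p = 0.319, Fisher's exact test). Of 6 root hair genes, 5 were higher in the authors' deposited table (adjusted p = 0.143, Fisher's exact test, with 4.06 of 5 from GC content and length), led by EXPA7 (log2 change 1.53) and LRX1 (1.51). Of 11 seed storage genes, 5 were higher and 2 lower in the authors' deposited table (adjusted p = 0.646, Fisher's exact test), with EM6 at a log2 change of -1.92 and SESA3 at 1.21. Of 9 stress genes, RAB18 fell by 2.08 while RD29A and HSP70 rose by log2 changes of 1.34 and 0.70 in the authors' deposited table.

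**Figure D2:**
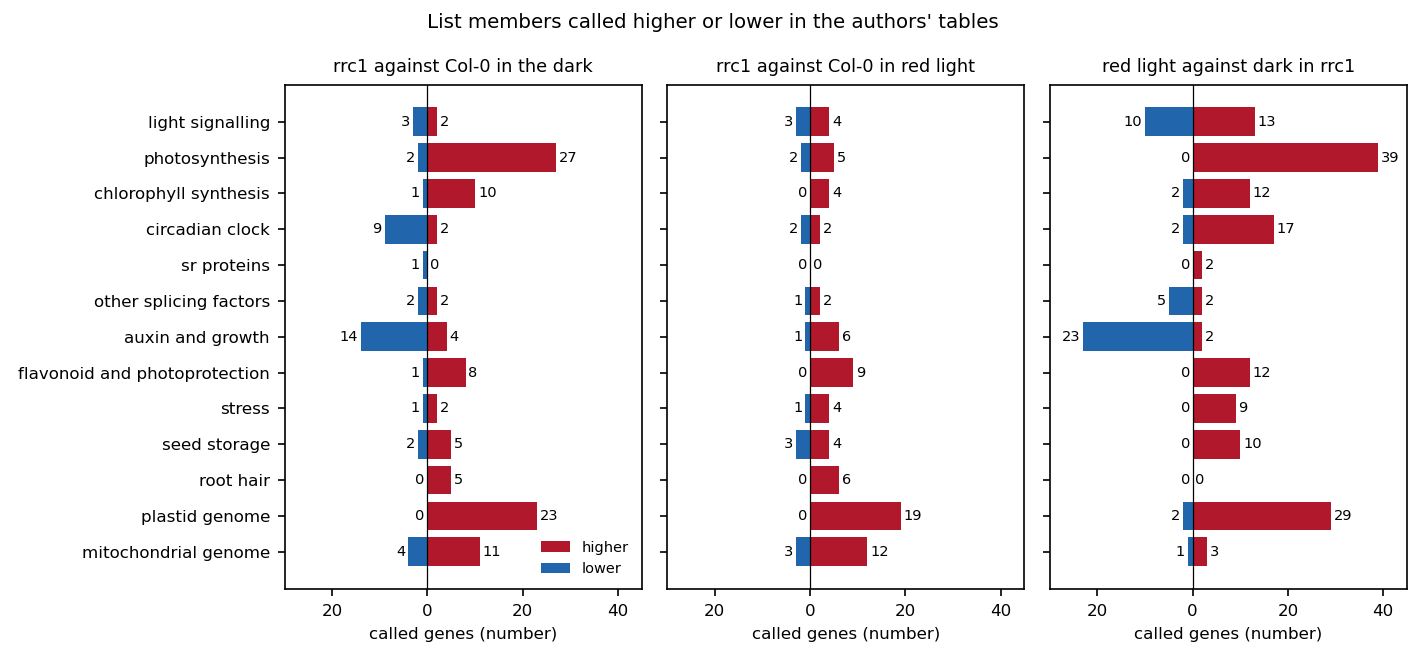
Number of members of 13 gene lists called higher (red, to the right) or lower (blue, to the left) in the authors' tables, for rrc1-3 against Col-0 in the dark, in red light, and for red light against dark in rrc1-3. Photosynthesis genes split 27 to 2 in the dark and 39 to 0 in the light response, and auxin and growth genes 4 to 14 and 2 to 23.

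By the rule for named genes, 8 genes per direction are also given, those with the largest changes among genes above the median level of the table. Besides FSD1 and plastid rRNA, the rises in the dark were in LCR85 (log2 change 3.58), HEC1 (2.88), the thylakoid calcium sensor CaS (2.66), AZI1 (2.62) and OEP6 (2.60) in the authors' deposited table. The largest falls were at AT3G21805 (log2 change -9.88), ALA8 (-9.61), AT5G13225 (-9.61), BHLH61 (346 to 0.674 FPKM), AT1G20015 (-8.33), AT1G12010 (-7.69), UBP27 (-7.29) and MRD1 (-5.87) in the authors' deposited table. Except for MRD1, these 8 regions contain annotated small nucleolar or small nuclear RNA genes, so their values may come from those RNAs. Of 46 called regions with such an RNA, 32 (69.6%) were lower in rrc1-3, against 44.5% of other called genes, per the authors' deposited table (two-sided Fisher's exact test, p = 0.000862). Relative to the shortest quintile by exon length of genes without such an RNA, the share lower differed by -5.01 points. Falls were thus not particular to these regions.

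The direction of change followed gene composition in both comparisons of rrc1-3 with Col-0. Genes in the lowest quintile of exon GC content were higher in rrc1-3 in 21.3% of cases in the dark, and those in the highest quintile in 80.1%, per the authors' deposited table. By exon length the share rose from 25.2% in the shortest to 79.1% in the longest quintile. Across genes, which are not independent replicates, the log2 change had a Spearman correlation of 0.399 with GC content and 0.334 with exon length. The tables hold called genes and pooled values only, so the spread between libraries could not be fitted.

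**Figure D3:**
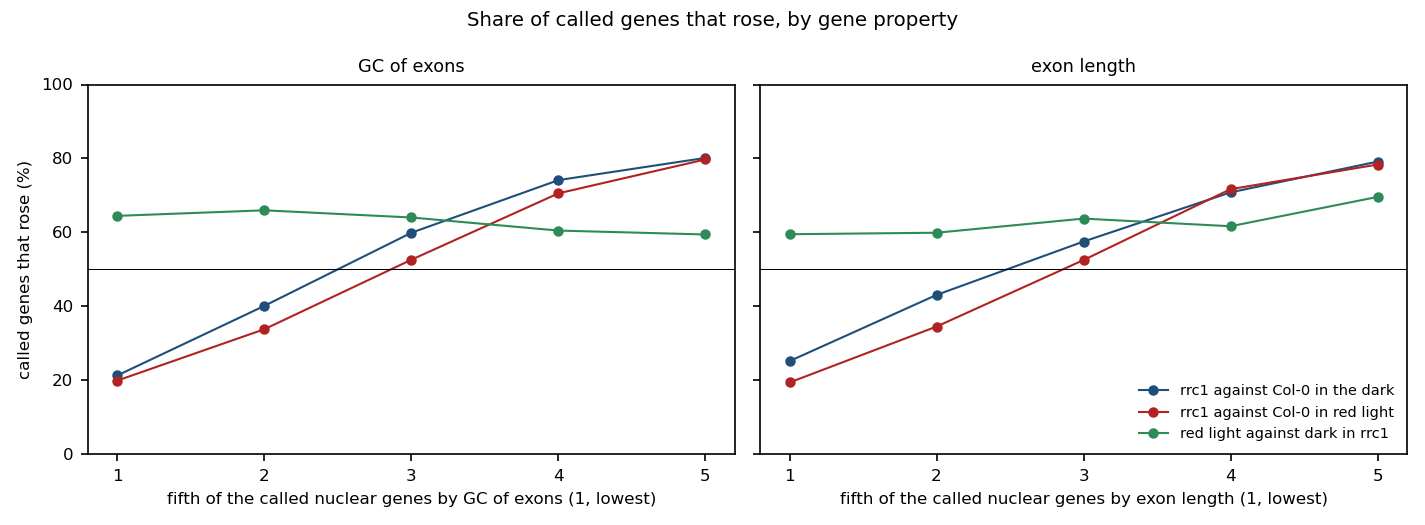
Share of called nuclear genes that rose (%), by quintile of exon GC content (left) and exon length (right), for each expression table; the horizontal line marks an equal split. Both comparisons of rrc1-3 with Col-0 climb from between 19.4% and 25.2% to between 78.3% and 80.1%, while red light against dark in rrc1-3 stays between 59.4% and 69.6%.

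In red light, the same genotype comparison asked which genes differed after 3 h of light. Of 12 flavonoid and photoprotection genes, 9 were called higher and 0 lower in rrc1-3, per the authors' deposited table (two-sided Fisher's exact test, adjusted p = 0.0212). ELIP1, an early light-induced protein of thylakoids, stood at 1286 FPKM in rrc1-3 and 265 in Col-0, and CHS at 164 against 32.0, in the authors' deposited table. FSD1 was again among the largest rises, 15.7-fold higher at 282 FPKM in the authors' deposited table. This authors' deposited table held 4031 genes, 2079 higher and 1952 lower in rrc1-3, of which 865 and 800 differed by at least a log2 of 1.

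From GC content and length alone, 5.09 of the 9 called flavonoid and photoprotection genes would be higher. FLS1, CHS, ELIP1 and the anthocyanin activator PAP1 rose by log2 changes of 2.87, 2.36, 2.28 and 1.99 in the authors' deposited table. Of 41 photosynthesis genes, 5 were higher and 2 lower in the authors' deposited table (adjusted p = 0.646, Fisher's exact test), with PSBY at 1.03 and LHCB2.3 at 0.83 on the log2 scale. Of 17 chlorophyll synthesis genes, 4 were higher and 0 lower in the authors' deposited table (adjusted p = 0.212, Fisher's exact test): PORA by a log2 of 2.50, PORB by 1.32, the chelatase activator GUN4 by 0.81 and the glutamyl-tRNA reductase HEMA1 by 0.71. Of 25 clock genes, ELF4 and GI rose by log2 changes of 1.25 and 0.73, and CDF1 and RVE8 fell by 0.81 and 0.70 in the authors' deposited table. Auxin and growth genes split 6 higher to 1 lower in the authors' deposited table (adjusted p = 0.212, Fisher's exact test), with EXPA11 at 0.90, GH3.3 at 0.75, the auxin carrier PIN3 at 0.66 and IAA4 at -0.71 on the log2 scale.

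Of 35 light signalling genes, 4 were higher and 3 lower in the authors' deposited table, among them PIL1 (log2 change 1.00), BBX20 (0.86), PAR1 (-0.76) and FHY1 (-0.65). No SR gene was listed, and of the other splicing factors GRP7 and PTB3 rose by log2 changes of 0.94 and 0.63 and LSM5 fell by 0.62 in the authors' deposited table. LSM5 and KAT5, a thiolase with a log2 change of 3.72, share a region in the authors' deposited table, so reads of either could count for both. COR15A, a cold-induced chloroplast protein, and RD29A rose by log2 changes of 3.18 and 1.91, and RAB18 fell by 1.39 in the authors' deposited table. The 9 stress genes split 4 higher to 1 lower in the authors' deposited table (adjusted p = 0.580, Fisher's exact test). All 6 root hair genes were higher in the authors' deposited table (adjusted p = 0.0779, Fisher's exact test, with 4.27 of 6 from GC content and length), and the 11 seed storage genes split 4 to 3. All 19 plastid-encoded genes called were higher (adjusted p = 3.97e-05, Fisher's exact test), and mitochondrial genes split 12 to 3 (adjusted p = 0.0836), in the authors' deposited table. The plastid changes reached a log2 of 10.1, and the limits given for plastid genes in the dark apply here too.

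Among genes above the median level, the largest rises in red light outside the plastid genome were in GH9B15 (log2 change 4.61), LCR85 (4.19), FSD1 (3.97), KAT5 (3.72) and FLS1 (2.87) in the authors' deposited table. At that level, the largest falls were at the U4 small nuclear RNA region AT3G06900 (log2 change -9.82), AT3G21805 (-9.74), AT1G12010 (-8.45), BHLH61 (-7.93), UBP27 (-7.60), MRD1 (-5.67), AT1G20015 (-5.42) and ADK1 (-5.41) in the authors' deposited table. Of 37 called regions with a small nucleolar or nuclear RNA, 30 (81.1%) were lower, against 48.1% of other called genes, per the authors' deposited table (two-sided Fisher's exact test, p = 4.96e-05). Relative to the shortest quintile by exon length of genes without such an RNA, the share lower differed by 1.18 points. The share of genes higher in rrc1-3 went from 19.9% in the lowest to 79.7% in the highest GC quintile, and from 19.4% to 78.3% by exon length, per the authors' deposited table.

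Genes listed in both conditions changed the same way. Of the genes shared by the dark and red light tables, 1570 were higher and 1483 lower in both, per the authors' deposited tables. The remaining 19 went in opposite directions, so that 99.4% of shared genes kept their direction. Independent lists of these sizes over 27432 protein-coding genes would share 236 higher and 179 lower genes, a background wider than the genes that could be called. The log2 change correlated with GC content alike in both comparisons (Spearman correlation 0.399 in the dark and 0.385 in red light). A difference in library preparation by genotype would also give shared directions, and it was not told apart from the mutation. LHCB1.4 was lower in the dark (log2 change -3.57) and higher in red light (0.64), and GH3.3, an auxin-conjugating enzyme, likewise (-1.03 and 0.75), per the authors' deposited tables. The difference between these responses was not tested, since values per library were not used here for gene expression. Reads of LHCB1.4 could also be shared with near-identical copies, so its reversal is uncertain.

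Red light against dark in rrc1-3 showed what 3 h of light changed in the mutant. Photosynthesis genes split 39 higher to 0 lower and flavonoid and photoprotection genes 12 to 0, while auxin and growth genes split 2 to 23, per the authors' deposited table. These splits differed from that of other called genes (two-sided Fisher's exact test, adjusted p = 4.28e-07, 0.0243 and 4.28e-07). LHCB1.4 reached 824 FPKM, a log2 change of 8.62, and LHCB1.1 went from 3.81 to 1436, while XTH15, a cell wall xyloglucan enzyme, went from 1776 to 118, in the authors' deposited table. Single values of LHCB1.4 and LHCB1.1 are uncertain, since reads could be shared among near-identical copies. The authors' deposited table held 5711 genes, 3595 higher and 2116 lower in red light, of which 1345 and 414 differed by at least a log2 of 1. A further 12 lower genes, listed at 0 in red light, and 1 higher gene, listed at 0 in the dark, have no finite log2 change and are left out of the 1345 and 414.

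From GC content and length alone, 7.12 of the 12 flavonoid and photoprotection genes and 14.5 of the 25 called auxin and growth genes would be higher. The log2 changes of ELIP1, ELIP2, F3H and LDOX, the last 2 of them flavonoid enzymes, were 6.71, 5.96, 5.55 and 5.17 in the authors' deposited table. Of 17 chlorophyll synthesis genes, 12 rose and 2 fell in the authors' deposited table (adjusted p = 0.190, Fisher's exact test), with CHLH at 3.54, CAO at 3.22, GUN4 at 3.14 and PORA at -1.65 on the log2 scale. Of 25 clock genes, 17 rose and 2 fell in the authors' deposited table (adjusted p = 0.0521, Fisher's exact test), led by CDF1 (log2 change 3.82), LNK1 (2.83), LHY (2.49) and PRR9 (2.38). Among auxin and growth genes in the authors' deposited table, the falls included XTH15, PRE5, IAA29 and SAUR22, by 3.91, 2.37, 2.22 and 1.94 on the log2 scale.

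Light signalling genes went both ways, 13 higher and 10 lower in the authors' deposited table (adjusted p = 0.681, Fisher's exact test). PIF7, a phytochrome-interacting factor, and SPA1, a partner of COP1, rose by log2 changes of 4.54 and 3.23, and the shade-induced PIL1 and ATHB2 fell by 3.52 and 3.05 in the authors' deposited table. SR45a and SCL30a, both SR genes, rose by log2 changes of 0.36 and 0.32, while other splicing factors split 2 higher to 5 lower in the authors' deposited table (adjusted p = 0.202, Fisher's exact test), GRP7 falling by 1.09. All 9 stress genes rose in the authors' deposited table (adjusted p = 0.0779, Fisher's exact test), COR15A by a log2 of 6.02. The seed storage genes rose in 10 cases and fell in 0 in the authors' deposited table (adjusted p = 0.0521, Fisher's exact test), though reads could be shared among SESA3 and its near-identical copies. No root hair gene was listed, plastid genes split 29 to 2 (adjusted p = 0.000802, Fisher's exact test) and mitochondrial genes 3 to 1 in the authors' deposited table. Other large rises were in the thionin THI2.2 (log2 change 7.71), AT1G60590 (6.66), AT1G48100 (5.89) and LHCB2.2 (5.79) in the authors' deposited table. Other large falls were in AT5G57760 (log2 change -5.38), the B-box gene BBX23 (-5.26), AT5G44260 (-4.05), GRF7 (-4.01), AT5G02540 (-3.69) and RTFL21 (-3.62) in the authors' deposited table. The share of genes that rose moved little with GC content here, from 64.5% to 59.4% over quintiles, per the authors' deposited table.

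The splicing comparison in the dark was read first at genes of RNA processing and the clock, lists whose share of listed genes was not tested. The first intron of SUA, a splicing factor of seed development, was retained in 4.91% ± 0.562 of reads in rrc1-3 and 12.2% ± 2.02 in Col-0 (SD, n = 3 each; edgeR log2 change in odds -1.44, adjusted p = 0.000743). An intron of the SR gene SR34b (chromosome 4, 1070887 to 1071273) was retained in 55.6% ± 4.49 against 75.9% ± 4.05 (SD, n = 3 each; edgeR log2 change in odds -1.33, adjusted p = 0.00322). The first coding intron of the clock gene RVE2 had a higher retained share, 73.2% ± 2.79 against 62.6% ± 0.947 (SD, n = 3 each; edgeR log2 change in odds 0.70, adjusted p = 0.00674). At this RVE2 intron, 128 nt from the 5′ end, both boundary and spliced reads were lower in rrc1-3 (log2 ratios -1.37 and -2.06). Its higher share thus rests on a larger fall of spliced reads. The authors' deposited table listed 6244 features in 4283 of 24197 genes with an annotated intron, of which 5847 were retained introns, 2820 with higher and 3027 with lower retention in rrc1-3.

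Features named by the smallest adjusted p in the table were mostly 5′ UTR introns. AT2G17500, a gene of the PIN-like auxin carriers, retained its first intron (chromosome 2, 7606871 to 7606943) in 49.5% ± 3.75 of reads in rrc1-3 and 69.0% ± 2.80 in Col-0 (SD, n = 3 each; edgeR adjusted p = 7.87e-05). RP1, a ribosomal protein gene, retained its first intron in 43.1% ± 3.05 against 18.2% ± 1.80 (SD, n = 3 each; edgeR adjusted p = 0.00247). At AKR2, a chaperone of chloroplast outer envelope proteins, use of the longer exon at an alternative 5′ splice site was 43.2% ± 3.81 against 59.6% ± 6.11 (SD, n = 3 each; edgeR adjusted p = 0.00166). The first intron of SAMDC, which overlaps AT3G02468, was retained in 64.0% ± 5.10 against 74.2% ± 2.18 (SD, n = 3 each; edgeR adjusted p = 0.0472), a call lost in each of the 6 runs that left out a library. Introns of NSP1, UGD2, OEP16-3 and emb1507, named by the same rule, did not pass the edgeR test (adjusted p = 0.136, 0.0523, 0.195 and 0.306).

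Of 35 light signalling genes, 10 had a listed feature and 5 a feature past the edgeR junction test. The alternative 3′ splice site of PIF1 was used in 79.1% ± 2.85 of reads in rrc1-3 and 86.4% ± 1.90 in Col-0 (SD, n = 3 each; edgeR adjusted p = 0.0281), a call lost in 4 of the 6 runs that left out a library. Features of PIF5, CRY2 and FHY3 did not pass (edgeR adjusted p = 0.0685, 0.354 and 0.248). Of 25 clock genes, 13 had a listed feature and 7 a feature past the junction test. BOA, a Myb-like clock factor, retained an intron in 5.66% ± 0.237 against 9.21% ± 1.31 of reads (SD, n = 3 each; edgeR adjusted p = 0.00972). RVE4 retained a coding intron in 7.85% ± 0.761 against 4.82% ± 0.695 (SD, n = 3 each; edgeR adjusted p = 0.0170, or 0.0591 without Col-0 replicate 3). An intron of LNK2, named by the same rule, did not pass (edgeR adjusted p = 0.324).

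Of 20 SR genes, 12 had a listed feature and 8 a feature past the junction test, with 13 introns higher and 7 lower. SR34a retained its first intron in 30.3% ± 7.44 of reads in rrc1-3 and 14.6% ± 2.05 in Col-0 (SD, n = 3 each; edgeR adjusted p = 0.00699). The third intron of SCL33 was retained in 41.7% ± 5.94 against 55.8% ± 1.44 (SD, n = 3 each; edgeR adjusted p = 0.00505). Of 27 other splicing factors, 11 had a listed feature and 10 a feature past the junction test, the mutated gene RRC1 itself in both counts. SKIP, a component that works in the clock and the spliceosome, retained its 5′ UTR intron in 8.86% ± 1.64 against 16.3% ± 1.01 (SD, n = 3 each; edgeR adjusted p = 0.00456). AFC2, a kinase of SR proteins, retained its first intron in 34.6% ± 5.04 against 52.4% ± 3.43 (SD, n = 3 each; edgeR adjusted p = 0.00285). In the authors' deposited pathway table, mRNA surveillance held 50 genes with changed splicing (Benjamini p = 9.5e-07) the spliceosome 56 (Benjamini p = 0.059) and the circadian rhythm pathway 12 (Benjamini p = 0.45).

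By class, 43.2% of 4770 plain introns had higher retention in rrc1-3, against 70.1% of 810 introns with an alternative event and 71.9% of 267 annotated retained introns. Over the 5847 retention features the share was 48.2% (exact two-sided binomial p = 0.00705, features not being independent replicates). With 1 feature per gene it was 50.6% (exact binomial p = 0.414), and among features past the edgeR test 49.2% (exact binomial p = 0.385), so the direction over all introns did not hold. Without 5′ UTR features the share was 41.5% (exact binomial p = 4.57e-32). In coding sequence 600 nt or more from the 5′ end it was 36.1% (exact binomial p = 7.42e-56), so lower retention led in these subsets. Alternative 3′ splice sites split 94 to 104 and alternative 5′ sites 63 to 85, while skipped exons were listed 0 higher to 25 lower and other exon features 0 to 26. With no exon feature of these classes listed as higher, a one-sided selection of the dark table cannot be ruled out, and these counts are not read as a direction. Of the 6244 features, 3353 passed the edgeR junction test (1629 higher, 1724 lower).

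The place of an intron in its transcript went with its direction. In the dark, 78.7% of 994 introns of 5′ UTRs had higher retention in rrc1-3, against 40.1% of 4387 coding introns and 37.0% of 146 introns of 3′ UTRs. Of the 782 introns of 5′ UTRs with higher retention, 754 had a negative log2 change of the feature in the authors' deposited table, so that change ran the other way. The same held for 1397 of all 2820 retention features with higher retention, and for RP1 (-1.60), SR34a (-0.91) and RVE2 (-0.56) in the authors' deposited table. Spliced reads across 5′ UTR introns were lower in rrc1-3, with a median log2 ratio of -0.83, and those across coding introns higher, at 0.59. Of unspliced boundary reads at 5′ UTR introns, 33.3% ± 1.05 lay on the boundary nearer the 5′ end in rrc1-3 and 41.0% ± 0.177 in Col-0 (SD, n = 3 each; exact permutation two-sided p = 0.1, the smallest that 3 against 3 allow).

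**Figure D4:**
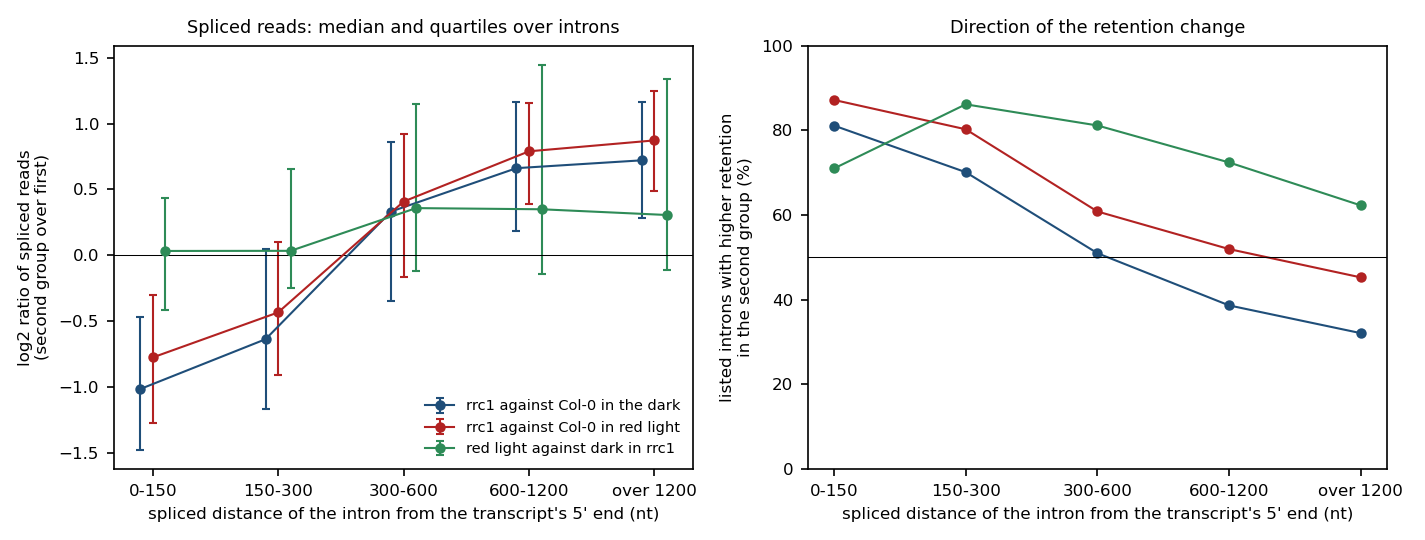
Listed introns by spliced distance from the 5′ end of the transcript (nt). Left, log2 ratio of spliced reads in the second group over the first (points, median over introns; bars, quartiles); right, listed introns with higher retention in the second group (%), which fell from 81.1% to 32.1% in the dark and from 87.1% to 45.3% in red light.

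In red light, the splicing comparison was again read at genes of light signalling and splicing, lists whose share of listed genes was not tested. PIF3, a central repressor of photomorphogenesis, retained a coding intron (chromosome 1, 3078611 to 3078842) in 6.41% ± 0.335 of reads in rrc1-3 and 11.6% ± 0.318 in Col-0 (SD, n = 3 each; edgeR log2 change in odds -0.94, adjusted p = 0.00305). AFC2 retained a coding intron (chromosome 4, 12755783 to 12755931) in 36.2% ± 2.78 against 22.2% ± 2.14 (SD, n = 3 each; edgeR log2 change in odds 0.99, adjusted p = 0.000505). The first intron of SUA was again retained less, in 6.55% ± 1.53 against 13.0% ± 1.96 (SD, n = 3 each; edgeR log2 change in odds -1.10, adjusted p = 0.00483). The authors' deposited table listed 6003 features in 4159 genes, of which 5542 were retained introns, 3352 with higher and 2190 with lower retention in rrc1-3.

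Among features named by smallest adjusted p, AT2G44060 retained its 5′ UTR intron in 36.3% ± 7.18 of reads in rrc1-3 and 11.5% ± 0.309 in Col-0 (SD, n = 3 each; edgeR adjusted p = 4.79e-05). AT3G62650 retained its 5′ UTR intron in 86.7% ± 3.80 against 94.5% ± 0.758 (SD, n = 3 each; edgeR adjusted p = 0.00257). AKR2 and AT2G17500 changed as in the dark, to 51.6% ± 2.74 from 64.0% ± 2.95 and to 57.7% ± 3.02 from 68.3% ± 6.20 (SD, n = 3 each; edgeR adjusted p = 0.00255 and 0.0124, the latter 0.0677 without Col-0 replicate 3). Features of NSP1, CINV1 and FSD1 did not pass (edgeR adjusted p = 0.410, 0.127 and 0.0800).

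Of 35 light signalling genes, 8 had a listed feature and 6 a feature past the junction test, with 10 introns higher and 1 lower. The first intron of PIF5 was retained in 54.5% ± 1.00 of reads in rrc1-3 and 43.8% ± 1.38 in Col-0 and that of CRY2 in 66.4% ± 7.04 and 57.5% ± 3.82 (SD, n = 3 each), neither past the test (edgeR adjusted p = 0.0521 and 0.0891), nor was an intron of PIF1 (edgeR adjusted p = 0.357). Of 25 clock genes, 14 had a listed feature and 10 a feature past the test. RVE2 retained its first intron in 60.8% ± 6.18 against 48.8% ± 2.56 (SD, n = 3 each; edgeR adjusted p = 0.0107, or 0.0548 without rrc1-3 replicate 2). The odds of the alternative 3′ splice site of LNK2 changed by a log2 of -0.69 (edgeR adjusted p = 0.00961, or 0.0530 without Col-0 replicate 3), and features of LHY and LNK1 did not pass (edgeR adjusted p = 0.12 and 0.117). Of 20 SR genes, 13 had a listed feature and 9 a feature past the test, with 18 introns higher and 6 lower. SR34b retained its intron in 67.9% ± 3.24 against 83.6% ± 3.61 (SD, n = 3 each; edgeR adjusted p = 0.00807), and features of RS2Z32 and SCL33 did not pass (edgeR adjusted p = 0.409 and 0.334). Of 27 other splicing factors, 13 had a listed feature and 12 a feature past the test, both counts again with RRC1 itself. The authors' deposited pathway table gave the spliceosome 61 genes with changed splicing at a fold enrichment of 1.61 (Benjamini p = 0.00935), and the circadian rhythm pathway 12 (Benjamini p = 0.487).

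Higher retention led in each intron class: 56.4% of 4433 plain introns, 76.9% of 837 introns with an alternative event and 75.7% of 272 annotated retained introns, 60.5% of 5542 together (exact two-sided binomial p = 3.16e-55, features not being independent replicates). Higher retention was found in 86.0% of 1027 introns of 5′ UTRs, in 53.3% of 4067 coding introns and in 48.0% of introns of 3′ UTRs (59 higher, 64 lower). For 824 of the 883 introns of 5′ UTRs with higher retention, AT2G44060 (-1.90), PIF5 (-0.61) and CRY2 (-0.74) among them, the log2 change of the feature in the authors' deposited table was negative. It was negative for the coding intron of RVE2 as well (-0.56) in the authors' deposited table. Among retention features 600 nt or more from the 5′ end in coding sequence it was 49.3% (exact binomial p = 0.463), so the lead did not hold there. Boundary reads at 5′ UTR introns lay on the 5′ side in 31.3% ± 0.389 of cases in rrc1-3 and 40.9% ± 0.207 in Col-0 (SD, n = 3 each; exact permutation two-sided p = 0.1, the smallest possible). Skipped exons split 40 higher to 24 lower in inclusion and other exon features 26 to 54. Of the 6003 features, 3453 passed the edgeR junction test, 2204 higher and 1249 lower.

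The dark and red light splicing tables shared 2376 features, of which 2224 (93.6%) changed the same way, 1269 higher and 955 lower. They shared 2380 genes, where independent lists over the 24197 genes with an annotated intron would share 736, a background wider than the genes that could be listed. A difference in library preparation by genotype would also give shared directions here, and it was not told apart from the mutation. For the 2349 shared features with the same junctions, an edgeR test asked whether the light response differed between genotypes. These features were listed for a genotype difference in both conditions, so those with a difference in 1 condition, where responses would differ most, were not tested. The test called 0 features, with 139 (5.92%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.0672. It called 3 features with the replicate block and 0 to 3 with a library left out. On simulated data it recovered 13% of changes of 1 and 81% of changes of 2 in log2 odds, so most differences of 1 would be missed. The simulation gave all features the same fixed dispersion and no genotype difference, so these rates may be too high. In the real data an estimated difference of -8.47 at AT5G37478 did not pass (edgeR adjusted p = 0.0672). The light response of these features passed the edgeR test at 53 features in Col-0 and 66 in rrc1-3, and the 30 that passed in both had the same direction.

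In rrc1-3, 7 of the 8 features with the smallest adjusted p between red light and dark were introns retained more in red light. The last intron of CA1, a chloroplast carbonic anhydrase (chromosome 3, 195338 to 195405), was retained in 25.4% ± 2.80 of reads in red light and 5.73% ± 0.699 in the dark (SD, n = 3 each; edgeR log2 change in odds 2.48, adjusted p = 1.09e-07). The 3′ UTR intron of CHLM, a chlorophyll synthesis methyltransferase, was retained in 54.1% ± 1.41 against 28.6% ± 1.97, and that of mtLPD1, a subunit of glycine decarboxylase, in 40.8% ± 2.76 against 12.8% ± 2.82 (SD, n = 3 each; edgeR adjusted p = 8.74e-06 and 2.41e-06). Retention also rose at GOX1 (12.4% ± 2.95 against 3.40% ± 0.484), GDCH (8.43% ± 0.774 against 2.57% ± 0.398) and GGT1 (6.61% ± 0.318 against 2.48% ± 0.126), enzymes of photorespiration, and at the carrier BOU (12.4% ± 2.53 against 5.92% ± 1.59; SD, n = 3 each). Spliced reads across these 7 introns also rose in red light, by log2 ratios from 0.895 (GDCH) to 2.34 (CA1). Boundary reads rose more, from 2.50 (CHLM) to 4.82 (CA1). Whether splicing itself changed at these introns was therefore not settled. In the authors' deposited table, 843 features in 643 genes were listed.

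Of 35 light signalling genes, PIF7 was the 1 with a listed feature. Its last intron was retained in 7.37% ± 0.992 of reads in red light and 52.3% ± 11.9 in the dark (SD, n = 3 each; edgeR log2 change in odds -3.79, adjusted p = 0.000111). Reads averaged 97.5 per library over both groups, with spliced reads higher in red light by a log2 of 5.18 and boundary reads by 1.44. The value in the dark thus rests on few reads. Of 25 clock genes, 7 had a listed feature, and 10 of their 11 retention features fell. LHY, LNK2 and LNK1 retained introns in 0.549% ± 0.108, 15.9% ± 2.13 and 8.53% ± 1.65 of reads, from 3.79% ± 2.09, 29.1% ± 5.18 and 16.9% ± 2.89 (SD, n = 3 each; edgeR adjusted p = 9.67e-05, 0.00318 and 0.00921). The exception was the last intron of RVE4, at 5.81% ± 1.08 from 2.59% ± 0.545 (SD, n = 3 each; edgeR adjusted p = 0.000321). Among splicing factors, the fourth exon of PTB2 was included in 19.2% ± 3.46 against 32.2% ± 2.75, and an intron of SCL30a was retained in 15.7% ± 2.32 against 25.0% ± 5.49 (SD, n = 3 each; edgeR adjusted p = 0.00159 and 0.0118). An HMG-box gene, AT1G76110, retained its last intron in 5.72% ± 0.393 against 30.8% ± 2.73 (SD, n = 3 each; edgeR adjusted p = 4.95e-06). Of 826 retention features, 612 (74.1%) were higher in red light (exact two-sided binomial p = 3.65e-45), 87.2% of 94 in 5′ UTRs and 71.8% of 678 in coding sequence. The edgeR junction test was passed by 731 of the 843 features, 537 higher and 194 lower.

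Changes in expression and in splicing fell on partly shared genes. In the dark, 997 genes were in both of the authors' deposited tables, 23.3% of the genes with changed splicing, and of these 584 were higher and 413 lower in expression. In red light, 629 genes were in both (358 higher, 271 lower), and for the light response in rrc1-3, 312 genes (231 higher, 81 lower), 48.5% of the genes with changed splicing. LNK2, LHY, PIF7 and PTB2 were among them in the light response. These overlaps were not tested, because the tables used here list called genes only.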

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

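The subsets by place in the transcript, small RNA genes, organelle genes and junction tests were chosen after results were seen. With an absolute log2 change of at least 1, called genes numbered 2509 (dark), 1665 (red light) and 1772 (light response, with 13 genes listed at 0 in a group). With that and a change of at least 10 points, splicing features numbered 796, 666 and 149, and with an adjusted p under 0.01 the light response held 518, all by construction of stricter thresholds. The edgeR junction test kept 3353 features in the dark and 3453 in red light. Leaving out each library gave 2470 to 2850, 2523 to 3003 and 649 to 701, and the replicate block 3331, 3234 and 734. The share of introns with higher retention in the dark was 50.6% with 1 feature per gene, reversed, and 49.2% among features past the junction test. It was 41.5% without 5′ UTR features and 36.1% in coding sequence 600 nt or more from the 5′ end, both in the main direction. In red light it was 49.3% (all classes) and 47.7% (plain introns) in coding sequence 600 nt or more from the 5′ end, both reversed; the cause was not tested. Leaving out each library gave shares of 47.8% to 48.4%, 60.0% to 60.6% and 73.8% to 74.5%. Genes changed in expression and splicing numbered 584 and 392 above the median level (dark, red light) and 196 at an adjusted p under 0.01 in both (light response), by construction. The test of differing light responses called 3 features with the replicate block and 0 to 3 with libraries left out (3 without rrc1_Dark replicate 3, 2 without Col_Dark replicate 1 or rrc1_Light replicate 3, 1 without Col_Light replicate 1 or rrc1_Dark replicate 2); the cause was not tested. Without organelle genes 5592, 3997 and 5676 genes remained, and without genes holding small RNAs 5584, 3994 and 5684. Of 64 named splicing features, 46 passed the junction test, 35 of them with each library left out in turn; 11 were lost and 6 others gained with a library left out, and the replicate block lost 2 (SAMDC and AFC1 in red light) and gained 1 (FSD1). Not run, since they need counts of genes per sample: DESeq2, RLE factors, no filter, one fit of all groups, organelle removal before normalization, camera, scaled counts of RRC1 and bin against gene counts. For gene expression, no paired analysis was possible because those tables hold 1 value per group.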

Other observations

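Of the tests below, those of transcript ends and of both intron boundaries were set before their values were seen, and the others, with the correlations for single ends, after the patterns were seen.

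Spliced reads across introns changed with place in the transcript. Across coding introns, the log2 ratio of spliced reads correlated with the distance to the nearest transcript end at 0.278 in the dark, 0.390 in red light and 0.0344 between light conditions in rrc1-3. That followed the distance to the 5′ end (0.272 and 0.358; to the 3′ end -0.0166 and 0.0651, or 0.00650 and 0.104 at equal 5′ distance), which argues against a loss from both ends in the dark. At 5′ UTR introns, reads over the boundary nearer the 5′ end changed by a median of -0.763 (dark), -0.861 (red light) and -0.0962 (light response) relative to the other boundary. Within genes, 5′ UTR introns changed relative to coding introns by -0.542 (184 genes) and -0.538 (156 genes) in boundary reads and by -1.27 and -1.28 in spliced reads. A loss near the 5′ end alone and such a loss with stronger retention cannot be told apart here, since features are listed for a change in the ratio of both kinds of reads, nor can the mutation and the preparation of libraries.

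Genes that fell in rrc1-3 had lower GC content and shorter exons than genes that rose. At equal GC content, exon length still correlated with the change at up to 0.271, which argues against GC content alone. At equal length, GC content correlated at up to 0.336, which argues against length alone. Between light conditions in rrc1-3 the correlation with GC content was -0.0283, as both preparation of libraries by genotype and the mutation would give, so these cannot be told apart.

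Regions with a small nucleolar or nuclear RNA were lower in rrc1-3. Among genes without one, the share that rose was lower in the shortest than in the longest quintile by exon length, at -53.8 points (dark), -58.2 (red light) and -9.91 (light response), as fewer reads from short nuclear transcripts would give. All 13 and 11 called plastid genes no longer than that shortest quintile were higher in rrc1-3 (dark, red light), which goes against such a loss for transcripts of any kind, unless they lie on longer shared transcripts, so this stays open. Compared with that shortest quintile, regions with a small RNA fell more often by -5.01 points in the dark and 1.18 in red light, which cannot tell an effect of the mutation on these RNAs from none.

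Other splits of the libraries were also tested with edgeR. In each table, 1 of 10 splits of the 6 libraries, the real one, gave as many features past the junction test (3353, 3453 and 731), with at most 1, 0 and 0 features in the others (dark, red light, light response). For 3 against 3 libraries this cannot go below 1 in 10. The features were also listed because the real groups differ, so low counts in other splits were built in and decide nothing. The difference of light responses was called at 0 features in edgeR (139 at an unadjusted p under 0.05), on features chosen for a genotype difference in both conditions, so that 100 of 100 draws had to give as many, which decides nothing. The highest other draw gave 368; draws exchange genotype labels within each light condition, so a draw can place the genotype difference on the tested term.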
